A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

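RNA levels were measured on 27 two-colour Agilent arrays, 1 array per sample, on 7 slides. Per the labels, total RNA of each culture was extracted with a Qiagen yeast kit, labelled indirectly with Cy3 and hybridised with Cy5-labelled genomic DNA. The DNA was that of the progenitor on 23 arrays and of BY4741 on the 4 arrays of BY4741 and RM11a. No dyes were swapped, so a dye effect shared by all arrays cancels only in differences between arrays. Each deposited scanner file gives intensity per spot for both dyes. Per the file headers, spots were read with Agilent Feature Extraction 10.5.1.1, which subtracted background with spatial and multiplicative detrending and applied no dye normalization to the processed intensity. Each array holds 6256 gene probes, 1 per gene, printed as 7 spots (43792 spots without controls). Of the systematic names in the files 5756 were matched to a reference table of locus names and 500 were not, and unmatched genes kept the name in the file.

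Control spots and spots marked as outliers in the files were left out (1.07 to 3.38% of spots per array), and saturated spots, of which no array had more than 1, were kept. Processed signals below an array's lowest signal among spots well above background were set to that signal. Then log2 of Cy3 over Cy5 was taken for each spot, the spots of a probe were averaged, and each array was centred on its median. No loess was applied, because against genomic DNA the log ratio follows expression, and it correlated with mean intensity at 0.683 to 0.858 across probes on each array. Before the data were examined, the sample groups, the tests, the gene lists, the rule for named genes and a set of alternative settings were fixed. The correction then planned for the main values was normexp with an offset of 50, with the processed signals as an alternative. The 2 were exchanged after the corrected values and the spread between replicates had been seen, and before any test. On Progenitor low glucose replicate 2, M8 low glucose replicate 2, M8 YPD replicate 1 and RM11a replicate 1, normexp left no Cy3 signal under 592, 1368, 2286 and 2143, against lowest processed signals of 23.8 to 38.3. A gene was tested if Cy3 was well above background (at least 4 of 7 spots) on all arrays of at least 1 group and Cy5 on every array of the fit, which left 6224 genes for the 23 arrays and 5754 for the 4. The Cy5 part of this filter was tightened after a first version, which asked it of 50% of the arrays, had been seen, and that version is among the alternatives.

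The deposited value table holds log2 values. Compared with the scanner values, the columns of the 23 arrays were log2 of Cy3 over Cy5 as medians of 7 spots without centring (r of at least 0.999 across genes, 96.5 to 99.95% of values within 0.2), so scale, centring and direction were settled for them. The columns of the BY4741 and RM11a arrays correlated at 0.456 to 0.464 with the scanner values, about as many genes matched as not (50.0 to 50.1% within 0.2), and they were not used here. For those 4 columns scale, centring and direction stay unknown. Column medians, by replicate, were for the progenitor -3.10 and -3.33 in high salt, -3.71 and -3.43 in low glucose and -3.52 and -3.59 in YPD. They were for S2 -3.60 and -3.43 in high salt, -1.998 and -0.38 in low glucose and -3.62 and -2.86 in YPD. They were for S6 -3.42 in high salt, -3.81 and -4.07 in low glucose and -3.97 and -3.62 in YPD. They were for M8 -2.97 and -3.28 in high salt, -1.74 and -2.01 in low glucose and -2.97 and -3.25 in YPD. The medians were -1.77 and -1.59 for BY4741 and -2.57 and -2.21 for RM11a.

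Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8). All 23 arrays against progenitor DNA entered 1 fit with a mean per strain and medium (11 residual and 2.75 prior degrees of freedom), and the BY4741 and RM11a arrays a fit of their own (2 and 3.25). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold change. The 19 comparisons were the progenitor in each stress against YPD, each evolved strain against the progenitor in each medium and averaged over media, S2 against M8, the difference of responses to a strain's own selective medium (high salt for S2 and S6, low glucose for M8), and RM11a against BY4741. The 28 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Members were also counted with the adjustment over the list alone. The lists of a-cell, alpha-cell, haploid and meiosis genes stood for other cell types that a culture could hold.

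In progenitor high salt, progenitor low glucose, the 4 averaged comparisons and RM11a against BY4741, the named genes were the 10 rising and 10 falling called genes with a symbol and the largest change whose arrays did not overlap within any medium. In the other comparisons 3 and 3 were named. Up to 4 called members with the largest change, or the 2 with the smallest p where none was called, served as examples of a list, and the genes of the adaptation study and the auxotrophic markers could be named in every comparison. Where a probe was well above background on no array of a group, the change reads "at least N-fold", but not in responses. The brighter group's mean was set against the dimmer's on the normalized log2 ratio. The dimmer's took, per array, the higher of the probe's signal and the array's lowest well above background. Such bounds are open to dye bias. A result that this rule would name is not reported here.

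The calling procedure was tested on simulated data with the spread of the real genes and 200 changed genes per comparison. It recovered 94 to 100% of changes of 1.5 log2 units and 100% of those of 3 in the 7 comparisons simulated, with at most 1 false call each. Array or slide shifts were not simulated. Cy3 signals lay well above background for 87.7 to 99.9% of probes per array and Cy5 signals for 6199 to 6256 probes, with median Cy5 signals of 1623 to 11636 over a background of 62 to 78. Of Cy3 spots, 0.0754 to 11.3% per array were set to the lowest signal well above background.

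The alternative settings fixed in advance were no background subtraction, loess, quantile normalization, Cy3 alone (normexp and quantile), the deposited value table, no filter and a strict filter on dim probes, a moderated variance with trend and robust estimation, no fold minimum, the replicate number as a block, a fit of only the arrays compared, slide as a random block in an additive model of strain and medium, and leaving out each array. Further alternatives, named with their effects in the closing section, were chosen after seeing the data.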

Results

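Messenger RNA levels of Saccharomyces cerevisiae were measured on 27 Agilent arrays with 6256 gene probes, each printed as 7 spots. On every array total RNA of a culture was labelled with Cy3 and genomic DNA with Cy5, so a gene's value is log2 of RNA over DNA signal, with the array's median set to 0. The progenitor and the evolved strains S2, S6 and M8 were each grown in YPD (the unstressed rich medium), in high salt and in low glucose, with 2 arrays per strain and medium except S6 in high salt, which had 1. The laboratory strain BY4741 and the vineyard-derived strain RM11a were grown in YPD, with 2 arrays each. From what is known of the study, S lines were propagated in high salt and M lines in low glucose, and the arrays were meant to show how mutations fixed there act on gene expression. The number of arrays limits the precision of every value. Median Cy3 signals ran from 506 to 1450 per array against a background of 19 to 22, and 5484 to 6252 of the 6256 probes lay well above background in Cy3. Replicate arrays correlated at 0.976 to 0.999 across genes, and the SD of their differences was widest for the progenitor in YPD (0.431) and S6 in low glucose (0.428). Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between samples that may be technical. Progenitor and S6 shared a slide in each medium, as did S2 and M8. S6 was therefore compared with the progenitor, and S2 with M8, within slides, whereas slide and strain cannot be told apart for S2 or M8 against the progenitor, nor slide and medium within a strain. Changes are log2 differences with their standard error (SE) from limma, and a called gene had a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold change. Of the fixed gene lists, counts adjusted over the list alone were the same as those over all genes unless given.

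The first comparison asked how the progenitor responded to high salt (2 arrays against 2). The largest increases were those of RTC3 at 4.06, TMA10 at 3.45, the hexose transporter HXT5 at 3.45, the stress protein HSP12 at 3.28 and the vitamin B6 synthesis genes SNO1 at 3.25 and SNZ1 at 2.79 (SE 0.092 to 0.26, adjusted p 8.0e-11 to 5.7e-07). Next came ARO5 at 3.25, CLD1 at 2.64, TMT1 at 2.57 and GPD1 at 2.64 (SE 0.091 to 0.19, adjusted p 3.6e-11 to 2.9e-07), the last a glycerol 3-phosphate dehydrogenase of glycerol synthesis. 11 of 22 osmostress (HOG) targets rose (list median 0.99, adjusted p = 0.011 with an estimated correlation), with the glycerol phosphatase GPP2 at 2.46 among them (SE 0.079, adjusted p 8.0e-11). 17 of 35 general stress (Msn2/Msn4) targets rose (list median 0.92, adjusted p = 0.035 with an estimated correlation), including the hexokinase HXK1 at 2.48 and DDR2 at 2.11 (SE 0.16 to 0.18, adjusted p 3.8e-07 to 4.9e-07). The sodium-efflux ATPase genes ENA2 at 1.75 and ENA1 at 1.54 rose (SE 0.12, adjusted p 1.6e-07 to 4.9e-07). 2 of 23 sodium and cation transport genes rose (list median -0.12, mean 0.0011, camera adjusted p = 0.69). Of the amino acid synthesis list, the arginine genes ARG1 at 2.50, ARG7 at 2.24 and ARG3 at 2.002 were examples that rose (SE 0.089 to 0.19, adjusted p 7.0e-10 to 6.0e-07). 18 of 65 amino acid biosynthesis genes rose (list median 0.50 but -0.0012 after loess, adjusted p = 0.17 with an estimated correlation). The siderophore uptake genes FIT2 at 2.16, of a cell wall protein, and ARN2 at 1.97, of a transporter, rose as well (SE 0.22 to 0.33, adjusted p 2.4e-05 to 3.7e-04). 9 of 25 iron regulon genes rose and 2 fell (list median 0.73, adjusted p = 0.17 with an estimated correlation).

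Among the largest decreases, mitochondrially encoded VAR1 at -1.98, COX2 at -1.74, COX3 at -1.72 and COX1 at -1.56 fell (SE 0.36 to 0.43, adjusted p 0.0031 to 0.0062), as did the acid phosphatase PHO5 at -1.86, PHM6 at -1.74, CSM4 at -1.76 and BRP1 at -1.63 (SE 0.16 to 0.35, adjusted p 3.8e-06 to 0.0036). ROF1 at least 3.14-fold lower and PFS1 at least 2.80-fold lower were not well above background in high salt (SE 0.24 to 0.43, adjusted p 1.5e-04 to 0.013). 6 of 8 mitochondrially encoded genes fell (list median -1.43, adjusted p = 0.37 with an estimated correlation). 4 of 16 phosphate (PHO) regulon genes fell (list median -0.49 but 0.14 after loess, adjusted p = 0.22 with an estimated correlation). 1 of 49 cell wall mannoprotein and hypoxic genes rose and 3 fell (list median -0.52 but 0.084 after quantile scaling and -0.013 with Cy3 alone, adjusted p = 0.66 with an estimated correlation), with TIR4 at -1.33 and TIR1 at -1.26 lower (SE 0.26 to 0.29, adjusted p 0.0020 to 0.0056). 5 of 22 haploid and pheromone genes fell (list median -0.37, adjusted p = 0.26 with an estimated correlation), with PRM1 at -1.11 and AGA1 at -1.10 among them (SE 0.20 to 0.25, adjusted p 0.0015 to 0.0054). 1 of 7 a-cell specific genes fell (list median -0.69 but 0.062 after loess, adjusted p = 0.22 with an estimated correlation), namely ASG7 at -1.31 (SE 0.29, adjusted p 0.0046). None of 25 meiosis and sporulation genes was called (list median -0.54 but -0.058 after quantile scaling, 0.13 after loess and -0.021 with Cy3 alone, 0 higher and 1 lower adjusted over the list alone, 15 at an unadjusted limma p below 0.05, adjusted p = 0.71 with an estimated correlation). 5 of 18 trehalose and glycogen genes rose (list median 0.58, adjusted p = 0.17 with an estimated correlation), with PGM2 at 1.93 and TSL1 at 1.77 highest (SE 0.12 to 0.15, adjusted p 9.4e-08 to 1.5e-06). 2 of 24 hexose transport and sensing genes rose and 1 fell (list median -0.36 but 0.013 after quantile scaling and 0.016 after loess, camera adjusted p = 0.46). 2 of 28 glucose-repressed carbon metabolism genes rose (list median -0.038 but 0.30 after quantile scaling, 0.072 after loess and 0.23 with Cy3 alone, mean 0.047, camera direction up, camera adjusted p = 0.53). 2 of 21 glycolysis and fermentation genes rose (list median 0.014, camera adjusted p = 0.40), namely TDH1 at 2.51 and ADH5 at 2.39 (SE 0.13 to 0.25, adjusted p 1.3e-08 to 7.9e-06). 1 of 36 oxidative phosphorylation genes rose (list median 0.10 but -0.0026 after loess, adjusted p = 0.71 with an estimated correlation). None of 19 tricarboxylic acid cycle genes was called (list median 0.21, 9 at an unadjusted limma p below 0.05, adjusted p = 0.55 with an estimated correlation). 3 of 6 auxotrophic marker genes rose (list median 0.88, adjusted p = 0.22 with an estimated correlation), with LYS2 at 1.43. Limma called 430 of 6224 genes, 137 higher and 293 lower, at median Cy3 level percentiles of 51.6 and 8.34. The split moved with the scaling, to 187 higher of 292 after quantile scaling and 1 higher and 0 lower after loess. With Cy3 alone it was 137 and 48, and 217 and 108 with processed Cy3.

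In low glucose against YPD (2 arrays against 2), the question was how the progenitor responded to the low-glucose medium. The sample titles write it as ymm, and the labels do not say whether it differed from YPD in glucose alone. The largest increase was that of HSP12 at 6.38 (SE 0.24, adjusted p 9.8e-11). The ammonium permease MEP2 at 5.92, the sulfate permease SUL1 at 4.90, the allantoin-use gene DAL3 at 4.51 and the general amino acid permease GAP1 at 4.34 also rose (SE 0.12 to 0.22, adjusted p 5.0e-13 to 4.7e-10). The high-affinity hexose transporter genes HXT7 at 4.55 and HXT6 at 4.47 rose, with DDR2 at 4.55, NRS1 at 4.63 and RTC2 at 4.46 (SE 0.16 to 0.26, adjusted p 6.0e-11 to 8.3e-09), while the low-affinity transporter gene HXT1 at -2.87 fell (SE 0.17, adjusted p 9.9e-09). 27 of 35 general stress (Msn2/Msn4) targets rose (list median 1.85, adjusted p = 0.028 with an estimated correlation). 14 of 22 osmostress (HOG) targets rose (list median 1.36, adjusted p = 0.034 with an estimated correlation), with MSC1 at 3.22 and RTC3 at 3.10 as further examples (SE 0.12 to 0.13, adjusted p 6.5e-11 to 3.3e-10). 13 of 18 trehalose and glycogen genes rose (list median 1.49, adjusted p = 0.040 with an estimated correlation), led by glycogen phosphorylase GPH1 at 3.44 (SE 0.14, adjusted p 1.9e-10). 24 of 36 oxidative phosphorylation genes rose (list median 1.15 but -0.0059 after loess, adjusted p = 0.057 with an estimated correlation). 7 of 19 tricarboxylic acid cycle genes rose (list median 0.83 but -0.054 after loess, adjusted p = 0.14 with an estimated correlation). Among the genes that rose were CYT1 at 1.98, QCR10 at 1.84, SDH2 at 1.96 and CIT1 at 1.71 (SE 0.10 to 0.16, adjusted p 1.1e-08 to 2.2e-07). None of 65 mitochondrial ribosomal protein genes was called (list median 0.17, 19 at an unadjusted limma p below 0.05, adjusted p = 0.43 with an estimated correlation). 16 of 29 sulfur and methionine genes rose and 2 fell (list median 1.27, adjusted p = 0.068 with an estimated correlation), among them SUL2 at 3.53, MET2 at 3.04 and MET28 at 3.03 (SE 0.086 to 0.12, adjusted p 6.5e-12 to 1.9e-10).

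The phosphate genes PHO12 at -4.94, PHO11 at -4.28, PHO84 at -3.88 and PHO89 at -3.81 fell in low glucose and were among the largest decreases of the comparison (SE 0.11 to 0.13, adjusted p 4.3e-12 to 1.4e-11). 2 of 16 phosphate (PHO) regulon genes rose and 13 fell (list median -2.39, adjusted p = 0.040 with an estimated correlation). Phosphate-responsive PHM7 at 3.85 rose (SE 0.32, adjusted p 3.9e-07). The amino acid permease genes BAP3 at -4.99, TAT1 at -4.40 and BAP2 at -4.00 fell, with the serine and threonine deaminase CHA1 at -5.27 and the flavohemoglobin YHB1 at -3.68 (SE 0.10 to 0.37, adjusted p 2.3e-12 to 4.1e-07). The siderophore transporter SIT1 at -3.74 and the ferric reductase FRE1 at -3.68 fell (SE 0.13 to 0.17, adjusted p 6.5e-11 to 6.6e-10). 16 of 25 iron regulon genes fell (list median -1.16, adjusted p = 0.068 with an estimated correlation). 8 of 108 ribosome biogenesis genes fell (list median -0.76, adjusted p = 0.15 with an estimated correlation), with NOP13 at -1.28 and ENP1 at -1.17 lower (SE 0.10 to 0.11, adjusted p 2.7e-07 to 1.6e-06). None of 137 cytosolic ribosomal protein genes was called (list median -0.60 but -0.12 after quantile scaling, 0.059 after loess and -0.18 with Cy3 alone, 127 at an unadjusted limma p below 0.05, adjusted p = 0.30 with an estimated correlation). 1 of 21 glycolysis and fermentation genes rose and 3 fell (list median -0.53 but -0.13 after quantile scaling, 0.0081 after loess and -0.17 with Cy3 alone, adjusted p = 0.50 with an estimated correlation), with hexokinase 2 gene HXK2 at -1.53 and enolase gene ENO2 at -1.22 lower (SE 0.15 to 0.20, adjusted p 1.4e-06 to 2.3e-04). 1 of 25 ergosterol biosynthesis genes fell (list median -0.47 but 0.021 after loess, adjusted p = 0.11 with an estimated correlation). 2 of 26 chaperone genes rose and 3 fell (list median -0.56 but 0.054 after loess, adjusted p = 0.50 with an estimated correlation). 3 of 49 cell wall mannoprotein and hypoxic genes rose and 4 fell (list median -0.16, camera adjusted p = 0.58), with ANB1 at -3.55 and TIR1 at -3.52 lowest (SE 0.18 to 0.29, adjusted p 2.2e-09 to 2.9e-07). 1 of 19 purine biosynthesis genes fell (list median 0.013, mean -0.065, camera adjusted p = 0.83). None of 25 meiosis and sporulation genes was called (list median 0.31, 7 at an unadjusted limma p below 0.05, adjusted p = 0.66 with an estimated correlation). None of 10 histone genes was called (list median 0.25 but -0.021 after loess, 5 at an unadjusted limma p below 0.05, adjusted p = 0.46 with an estimated correlation). 5 of 24 hexose transport and sensing genes rose and 2 fell (list median 0.012 but -0.054 after quantile scaling, camera adjusted p = 0.41). Limma called 495 of 6224 genes, 326 higher and 169 lower, and 476 (327 higher and 149 lower) with Cy3 alone. After loess, which flattens expression differences against a DNA reference, the split was 2 higher and 4 lower.

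**Figure D1:**
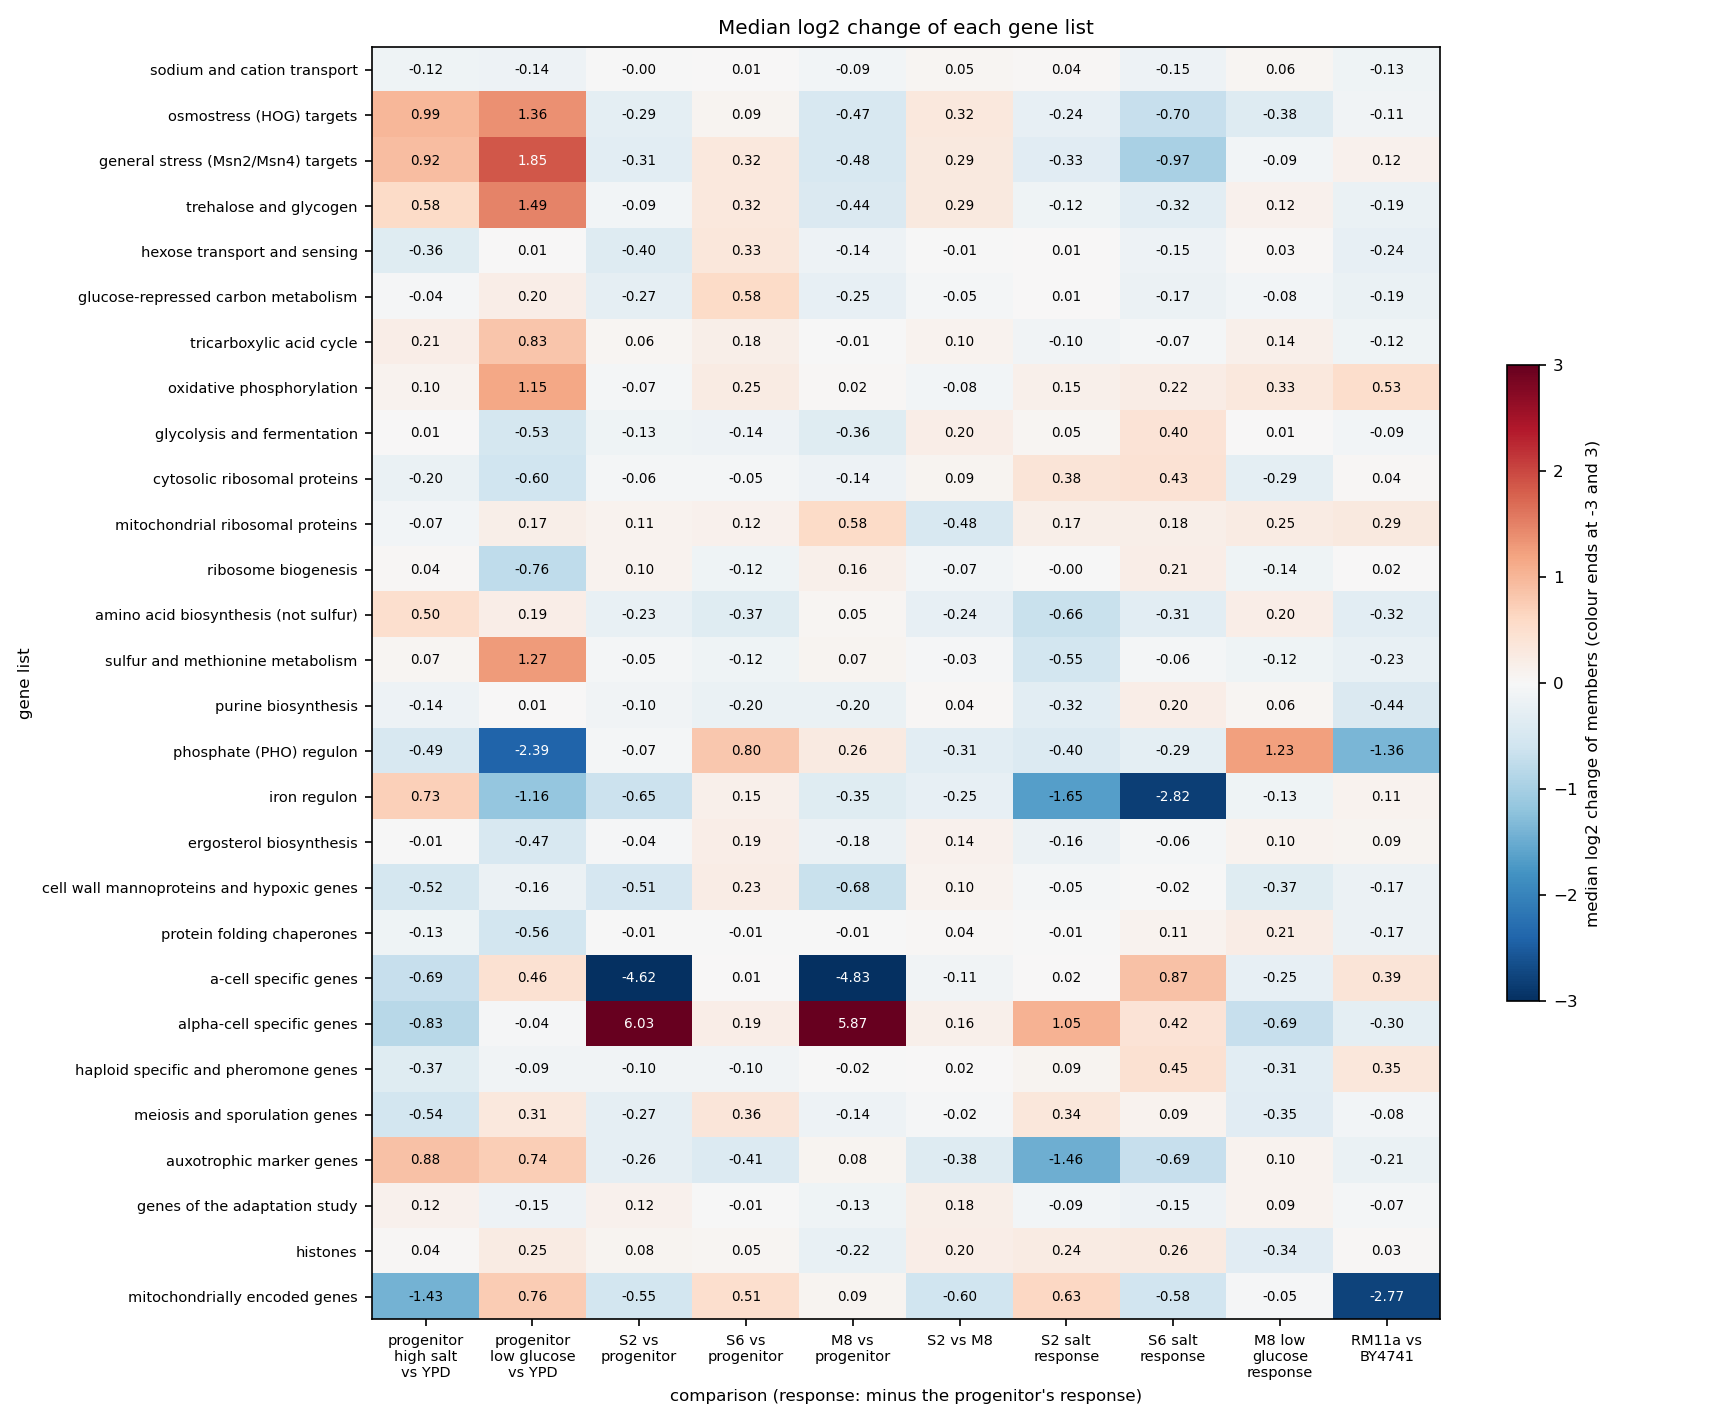
Median log2 change of each of the 28 gene lists (vertical axis) in 10 comparisons (horizontal axis), with colours ending at -3 and 3 and "response" meaning a strain's response minus the progenitor's. The a-cell lists of S2 and M8 lie at -4.62 and -4.83, and the alpha-cell lists at 6.03 and 5.87, with the same sign under quantile, loess and Cy3 scaling.

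S2 was compared with the progenitor to find expression changes in a salt-evolved strain, first averaged over the 3 media (6 arrays against 6). Genes specific to alpha cells were higher, and genes specific to a cells lower, than in the progenitor. The alpha-factor genes MF(ALPHA)1 at least 261-fold higher and MF(ALPHA)2 at 6.59, the a-factor receptor gene STE3 at least 43.1-fold higher, AFB1 at 3.29, the alpha-agglutinin gene SAG1 at 2.90 and the mating-type genes MATALPHA1 at 1.44 and HMLALPHA1 at 1.37 were higher in S2 (SE 0.10 to 0.33, adjusted p 4.3e-13 to 1.6e-06). Lower were the a-factor genes MFA2 at -7.16 and MFA1 at -5.11, the alpha-factor receptor gene STE2 at -5.84, the a-agglutinin subunit AGA2 at -4.62 and HMRA1 at least 21.7-fold lower (SE 0.055 to 0.19, adjusted p 1.3e-17 to 7.4e-10), and also BAR1 at -3.87, STE6 at -3.81 and ASG7 at least 4.67-fold lower (SE 0.069 to 0.17, adjusted p 3.3e-14 to 2.6e-07). 4 of 4 alpha-cell specific genes were higher (list median 6.03, adjusted p = 0.0054 with an estimated correlation). 7 of 7 a-cell specific genes were lower (list median -4.62, adjusted p = 0.0063 with an estimated correlation). Outside the mating genes, the sodium-efflux ATPase ENA2 at 1.29 was higher (SE 0.068, adjusted p 1.3e-08), while vitamin B6 gene SNO1 at least 4.52-fold lower and HOP2 at -1.91 were lower (SE 0.15 to 0.18, adjusted p 1.2e-07 to 6.6e-06). 8 of 49 cell wall mannoprotein and hypoxic genes were lower (list median -0.51 but -0.034 after quantile scaling and 0.045 with Cy3 alone, adjusted p = 0.66 with an estimated correlation), with PAU13 at -1.55 lowest (SE 0.15, adjusted p 6.6e-06). 4 of 25 iron regulon genes were lower (list median -0.65, adjusted p = 0.080 with an estimated correlation), with FIT2 at -1.30 lowest (SE 0.19, adjusted p 2.1e-04). Without the 11 genes of the a-cell and alpha-cell lists, 109 (6 higher and 103 lower) were called, which still count AFB1, MATALPHA1, HMLALPHA1 and HMRA1. Limma called 120 of 6224 genes, 10 higher and 110 lower, and with slide as a random block 67 (9 higher and 58 lower). Under other scalings the split was 12 higher and 26 lower after quantile scaling, 62 higher and 32 lower after loess and 14 higher and 34 lower with Cy3 alone, and the count was 83 without Progenitor YPD replicate 1 and 235 without Progenitor YPD replicate 2.

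Within high salt (2 arrays against 2), S2 again differed most in MF(ALPHA)1 at least 437-fold higher, MF(ALPHA)2 at 7.54, STE3 at least 103-fold higher, MFA2 at -7.71, STE2 at -6.12 and MFA1 at -5.07 (SE 0.10 to 0.57, adjusted p 1.3e-14 to 6.9e-08). 20 of 25 iron regulon genes were lower (list median -1.29, 0 higher and 21 lower adjusted over the list alone, adjusted p = 0.0037 with an estimated correlation), with FIT2 at -4.18, ARN2 at -3.69 and FIT3 at -3.11 furthest down (SE 0.22 to 0.37, adjusted p 3.6e-08 to 3.8e-05). The arginine genes ARG3 at -3.62, ARG1 at -3.62 and ARG4 at -2.36 were lower (SE 0.092 to 0.19, adjusted p 1.6e-11 to 1.0e-08). 19 of 65 amino acid biosynthesis genes were lower (list median -0.56 but 0.075 after loess, adjusted p = 0.11 with an estimated correlation). The glycerol symporter gene STL1 at 2.20 was higher, while HXT5 at -3.37 and ADH5 at -3.21 were lower (SE 0.13 to 0.27, adjusted p 3.6e-10 to 6.3e-05). In low glucose MF(ALPHA)1 at 7.51, MF(ALPHA)2 at 5.78, STE3 at 3.86, MFA2 at -6.80, AGA2 at -5.99 and MFA1 at -5.21 led (SE 0.18 to 0.57, adjusted p 7.0e-12 to 1.4e-06), and ENA2 at 1.52 was higher (SE 0.12, adjusted p 1.9e-06). Of mitochondrially encoded genes, COX1 at -1.67 and OLI1 at -1.56 were lower (SE 0.29 to 0.37, adjusted p 8.0e-04 to 0.0022). 7 of 8 mitochondrially encoded genes were lower (list median -1.38 but 0.074 after loess, adjusted p = 0.90 with an estimated correlation). 20 of 49 cell wall mannoprotein and hypoxic genes were lower (list median -0.91 but -0.012 after quantile scaling and 0.12 with Cy3 alone, 0 higher and 22 lower adjusted over the list alone, adjusted p = 0.90 with an estimated correlation). The median over all genes was -0.13 for the ratio and 0.028 for Cy3 alone in this comparison. In YPD MF(ALPHA)1 at 7.81, MF(ALPHA)2 at 6.46, STE3 at 5.75, MFA2 at -6.97, STE2 at -5.62 and MFA1 at -5.04 again led (SE 0.10 to 0.57, adjusted p 4.2e-14 to 9.5e-07). Next to them ENA2 at 2.07 and ENA1 at 1.76 were higher (SE 0.12, adjusted p 5.8e-08 to 3.9e-07). 2 of 10 genes of the adaptation study were higher (list median 0.23, adjusted p = 0.040 with an estimated correlation). Calls numbered 195 in high salt (22 higher and 173 lower), or 61 and 8 after loess. Low glucose gave 603 (38 higher and 565 lower), or 132 and 160 after quantile scaling and 235 and 371 after loess. Cy3 alone gave 21 and 43 and processed Cy3 37 and 70. YPD gave 42 (13 higher and 29 lower), or 19 and 24 after quantile scaling and 66 and 9 after loess. The YPD count was 28 without S2 YPD replicate 2 and 246 without Progenitor YPD replicate 2.

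**Figure D2:**
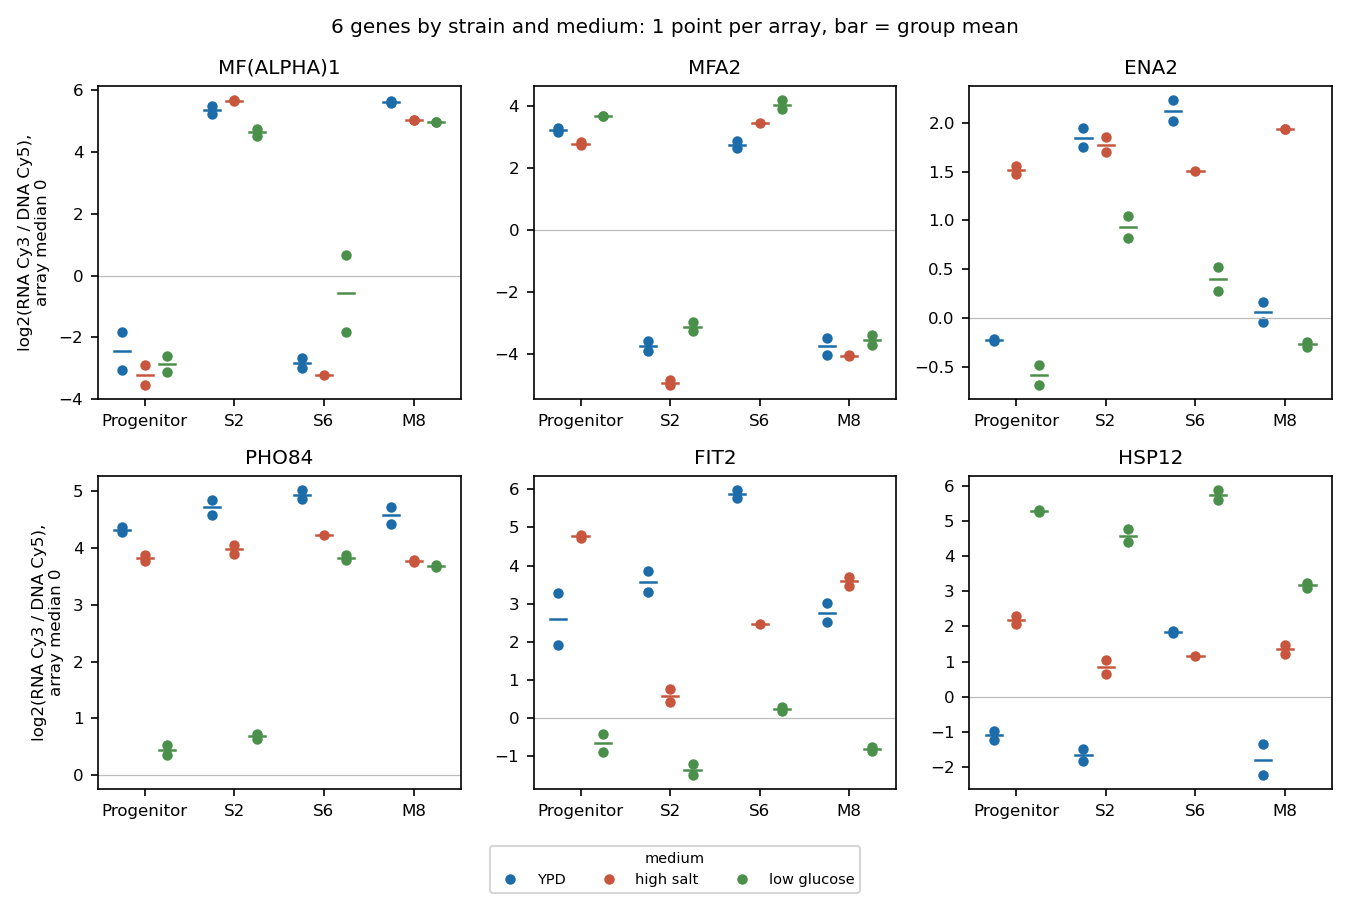
Level of MF(ALPHA)1, MFA2, ENA2, PHO84, FIT2 and HSP12 (vertical axis, log2 of RNA over DNA signal, array median 0) in each strain and medium (horizontal axis), with 1 point per array and a bar at the group mean. Averaged over media, MFA2 differed from the progenitor by -7.16 in S2 and was at least 129-fold lower in M8.

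S6, the other salt-evolved strain, was compared with the progenitor on the same slides (5 arrays against 6 over the media). Higher in S6 were the phosphate transporter PHO89 at 2.76, the glycerol symporter STL1 at 2.73 and the dipeptide transporter PTR2 at 2.55, with HUG1 at 2.51, HES1 at 2.47 and TMA10 at 2.32 (SE 0.074 to 0.19, adjusted p 4.2e-12 to 2.1e-07). Next came the transcriptional activator gene GAL4 at 2.19, ECM13 at 2.13, the pyruvate carrier gene MPC3 at 2.11 and RSB1 at 2.10 (SE 0.080 to 0.50, adjusted p 2.2e-10 to 0.0062). Both sodium-efflux ATPase genes ENA2 at 1.11 and ENA1 at 1.06 were higher (SE 0.073 to 0.074, adjusted p 6.6e-08 to 9.9e-08). The asparaginase genes ASP3-1 at -2.60, ASP3-2 at -2.60, ASP3-3 at -2.59 and ASP3-4 at -2.58, a tandem repeat of near-identical copies that share signal, were lower by like amounts (SE 0.062 to 0.069, adjusted p 3.5e-12 to 4.2e-12). Also lower were COS8 at -1.94, COS1 at -1.17, the arginine synthesis gene ARG3 at -1.49, AGA1 at -1.12, AIF1 at -1.07 and the IMP dehydrogenase IMD2 at -1.06 (SE 0.056 to 0.13, adjusted p 9.2e-10 to 1.9e-05). 8 of 16 phosphate (PHO) regulon genes were higher (list median 0.80, adjusted p = 0.030 with an estimated correlation), with PHO5 at 2.09 and GIT1 at 1.56 (SE 0.12 to 0.13, adjusted p 9.5e-09 to 5.3e-07). 10 of 28 glucose-repressed carbon metabolism genes were higher (list median 0.58, adjusted p = 0.030 with an estimated correlation), with the regulator ADR1 at 2.07, REG2 at 1.61 and the alcohol dehydrogenase ADH2 at 1.56 highest (SE 0.060 to 0.36, adjusted p 9.8e-12 to 0.0061). 4 of 65 amino acid biosynthesis genes were lower (list median -0.37 but 0.013 after loess, adjusted p = 0.21 with an estimated correlation), with ARG1 at -2.28 lowest (SE 0.12, adjusted p 6.0e-09). 6 of 35 general stress (Msn2/Msn4) targets were higher (list median 0.32, adjusted p = 0.29 with an estimated correlation), including ALD4 at 1.44 (SE 0.058, adjusted p 4.0e-10). None of 7 a-cell specific genes was called (list median 0.0096 but -0.18 after quantile scaling, -0.0078 after loess and -0.10 with Cy3 alone, mean -0.13, camera direction down, 2 at an unadjusted limma p below 0.05, camera adjusted p = 0.40). None of 4 alpha-cell specific genes was called (list median 0.19 but -0.033 with Cy3 alone, 0 at an unadjusted limma p below 0.05, camera adjusted p = 0.55). Limma called 139 of 6224 genes, 113 higher and 26 lower, and 133 (119 higher and 14 lower) with slide as a random block. After loess the split was 0 higher and 2 lower.

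In high salt, where S6 had 1 array that is taken to vary like the other groups, STL1 at 5.09, GAL4 at 2.66 and IMA1 at 2.60 were higher and ARG1 at -4.76, SNO1 at -4.22 and ARN2 at -4.08 lower (SE 0.19 to 0.33, adjusted p 1.0e-08 to 1.6e-06). 16 of 25 iron regulon genes were lower (list median -1.46, 0 higher and 17 lower adjusted over the list alone, adjusted p = 0.0082 with an estimated correlation). 1 of 35 general stress (Msn2/Msn4) targets was higher and 4 were lower (list median -0.17, adjusted p = 0.76 with an estimated correlation). In low glucose (2 arrays against 2), phosphate genes PHO89 at 4.53, PHO5 at 4.39 and PHO84 at 3.39 were higher with PTR2 at 4.26 (SE 0.11 to 0.23, adjusted p 1.5e-11 to 1.4e-08). 9 of 16 phosphate (PHO) regulon genes were higher (list median 1.65, adjusted p = 0.013 with an estimated correlation). The repeat genes ASP3-1 at -2.66, ASP3-3 at -2.64 and ASP3-2 at -2.62 were lowest (SE 0.10 to 0.11, adjusted p 7.0e-10 to 8.4e-10). 11 of 25 meiosis and sporulation genes were higher (list median 0.97 but -0.090 after loess, 12 higher and 0 lower adjusted over the list alone, adjusted p = 0.49 with an estimated correlation). 1 of 4 alpha-cell specific genes was higher (list median 0.70 but -0.10 after loess and 0.076 with Cy3 alone, camera adjusted p = 0.23). The 267 higher calls lay at a median Cy3 level percentile of 13.2, so raised dim signals on S6 arrays stay open. MF(ALPHA)1 at 2.29 was higher too (SE 0.57, adjusted p 0.010). Its level was 0.68 and -1.82 on the S6 and -3.12 and -2.61 on the progenitor arrays. In YPD TMA10 at 4.54, HES1 at 3.57 and FIT3 at 3.46 were the highest and ASP3-1 at -2.64, ASP3-2 at -2.63 and COS8 at -2.63 the lowest (SE 0.10 to 0.37, adjusted p 8.8e-10 to 1.1e-05). 18 of 25 iron regulon genes were higher (list median 1.32, 19 higher and 0 lower adjusted over the list alone, adjusted p = 0.010 with an estimated correlation), with FIT2 at 3.27 and FRE5 at 2.87 (SE 0.33 to 0.34, adjusted p 7.6e-06 to 2.7e-05). 10 of 35 general stress (Msn2/Msn4) targets were higher (list median 0.61, adjusted p = 0.039 with an estimated correlation), with HSP12 at 2.94 and HXK1 at 2.72 (SE 0.18 to 0.24, adjusted p 1.4e-07 to 7.8e-07). 11 of 28 glucose-repressed carbon metabolism genes were higher (list median 0.53, adjusted p = 0.044 with an estimated correlation). 1 of 7 a-cell specific genes was lower (list median -0.59, adjusted p = 0.19 with an estimated correlation), namely BAR1 at -1.27 (SE 0.18, adjusted p 1.4e-04). Limma called 215 genes in high salt (78 higher and 137 lower) and 202 in YPD (163 higher and 39 lower). After loess YPD gave none, with 619 at an unadjusted p below 0.05. Low glucose gave 287 (267 higher and 20 lower), or 246 and 117 after quantile scaling and 1 and 7 after loess. Cy3 alone gave 162 and 34 and processed Cy3 284 and 140.

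M8, from the low-glucose line, was compared with the progenitor over the 3 media (6 arrays against 6). As in S2, alpha-cell genes were higher, with MF(ALPHA)1 at least 259-fold higher, MF(ALPHA)2 at 6.40, STE3 at least 39.4-fold higher, AFB1 at 3.28, SAG1 at 2.47, MATALPHA1 at 1.31 and HMLALPHA1 at 1.23 higher (SE 0.10 to 0.33, adjusted p 5.9e-13 to 2.1e-06). Lower were MFA2 at least 129-fold lower, STE2 at -5.58, MFA1 at -5.27, AGA2 at -4.83, HMRA1 at least 23.8-fold lower, STE6 at -3.83, BAR1 at -3.70 and ASG7 at least 4.44-fold lower (SE 0.055 to 0.19, adjusted p 2.5e-17 to 2.8e-07). 4 of 4 alpha-cell specific genes were higher (list median 5.87, adjusted p = 0.014 with an estimated correlation). 7 of 7 a-cell specific genes were lower (list median -4.83, adjusted p = 0.019 with an estimated correlation). Outside the mating genes, CIS1 at 1.38, PET117 at 1.13 and MRP35 at 1.09 were higher (SE 0.13 to 0.15, adjusted p 4.4e-06 to 4.9e-05), and the cell wall mannoprotein gene CWP1 at -1.81 and CCW22 at -1.91 lower (SE 0.10, adjusted p 1.9e-08 to 2.3e-08). Of nuclear genes for the mitochondrial ribosome, 65 of 65 had a positive change. 1 of 65 mitochondrial ribosomal protein genes was higher (list median 0.58, adjusted p = 0.025 with an estimated correlation), and the called member was MRPL24 at 1.09 (SE 0.070, adjusted p 8.3e-08). 7 of 49 cell wall mannoprotein and hypoxic genes were lower (list median -0.68 but -0.15 after quantile scaling and -0.034 with Cy3 alone, adjusted p = 0.54 with an estimated correlation), with TIR1 at -1.77 also lower (SE 0.17, adjusted p 2.7e-06). 4 of 35 general stress (Msn2/Msn4) targets were lower (list median -0.48, adjusted p = 0.29 with an estimated correlation), with HSP12 at -1.21 and TKL2 at least 2.18-fold lower lowest (SE 0.13 to 0.14, adjusted p 1.3e-05 to 1.6e-05). TKL2 lay at 0.025 after normexp. 3 of 16 phosphate (PHO) regulon genes were higher and 1 was lower (list median 0.26, adjusted p = 0.29 with an estimated correlation), including PHO89 at 1.24 and PHO84 at 1.15 higher and PHM7 at -1.19 lower (SE 0.065 to 0.19, adjusted p 2.1e-08 to 1.6e-04). Without the 11 genes of the a-cell and alpha-cell lists 217 (16 higher and 201 lower) were called, AFB1, MATALPHA1, HMLALPHA1 and HMRA1 still among them. Limma called 228 of 6224 genes, 20 higher and 208 lower, and 168 (16 higher and 152 lower) with slide as a random block. Under other scalings the split was 29 higher and 37 lower after quantile scaling, 62 higher and 29 lower after loess and 17 higher and 33 lower with Cy3 alone, and the count was 123 without Progenitor YPD replicate 1 and 371 without Progenitor YPD replicate 2.

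Within high salt (2 arrays against 2), M8 differed most in MF(ALPHA)1 at least 285-fold higher, STE3 at least 50.2-fold higher, MF(ALPHA)2 at 4.68, MFA2 at -6.84, STE2 at -5.49 and HMRA1 at least 25.7-fold lower (SE 0.10 to 0.57, adjusted p 5.7e-14 to 5.0e-07). The mannoprotein genes CWP2 at -1.72 and CWP1 at -1.60 and phosphate gene PHM6 at -2.94 were lower (SE 0.14 to 0.18, adjusted p 6.2e-08 to 4.8e-05). 11 of 25 iron regulon genes were lower (list median -0.94, adjusted p = 0.13 with an estimated correlation). None of 65 mitochondrial ribosomal protein genes was called (list median 0.51, 55 at an unadjusted limma p below 0.05, adjusted p = 0.035 with an estimated correlation). In low glucose MF(ALPHA)1 at 7.84, MF(ALPHA)2 at 7.005, STE3 at 4.39, MFA2 at least 149-fold lower, AGA2 at -6.69 and MFA1 at -6.13 led (SE 0.18 to 0.57, adjusted p 3.1e-12 to 3.9e-07). Phosphate genes PHO84 at 3.25, SPL2 at 3.09, PHO89 at 2.71 and PHO12 at 2.67 were higher (SE 0.11 to 0.16, adjusted p 1.4e-10 to 1.1e-08). 9 of 16 phosphate (PHO) regulon genes were higher and 1 was lower (list median 1.51, adjusted p = 0.034 with an estimated correlation). 12 of 65 mitochondrial ribosomal protein genes were higher (list median 0.75, adjusted p = 0.043 with an estimated correlation), with MRPL17 at 1.62 and MRP21 at 1.61 highest (SE 0.094 to 0.17, adjusted p 3.7e-08 to 9.6e-06). The stress genes HSP12 at -2.11 and FMP16 at -2.11 were lower, whereas hexose transporter gene HXT4 at 1.93 was higher (SE 0.16 to 0.24, adjusted p 1.6e-06 to 1.6e-05). The median over all genes was -0.11 for the ratio and 0.0084 for Cy3 alone. In YPD MF(ALPHA)1 at 8.06, MF(ALPHA)2 at 7.53, STE3 at 5.86, MFA2 at -6.97, STE2 at -5.50 and MFA1 at -5.07 led (SE 0.10 to 0.57, adjusted p 5.5e-14 to 9.0e-07). The enolase gene ENO1 at -2.07, CWP1 at -1.92 and HXK1 at -1.52 were lower and hypoxic gene ANB1 at 1.62 higher (SE 0.18 to 0.24, adjusted p 1.5e-05 to 1.6e-04). Calls were 106 in high salt (37 higher and 69 lower), or 35 and 41 after quantile scaling and 44 and 2 after loess. Low glucose gave 676 (96 higher and 580 lower), or 203 and 214 after quantile scaling and 256 and 355 after loess. Cy3 alone gave 34 and 69 and processed Cy3 100 and 127. YPD gave 145 (26 higher and 119 lower), or 51 and 39 after quantile scaling and 73 and 7 after loess. Cy3 alone gave 27 and 35. The YPD count was 70 without Progenitor YPD replicate 1 and 445 without Progenitor YPD replicate 2, and 226 and 85 without M8 YPD replicate 1 and 2. S2 and M8 shared 9 higher and 61 lower calls over the media, where independent lists would share 0.0321 and 3.68. Across genes, which are not independent replicates, their changes correlated at 0.812 (0.747 without cell-type genes). Unchanged strains simulated against the same arrays gave 0.498. The covariance was 0.149 against a simulated 0.00724, and the correlation was 0.740 with the progenitor arrays split between the strains, which also share slides.

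**Figure D3:**
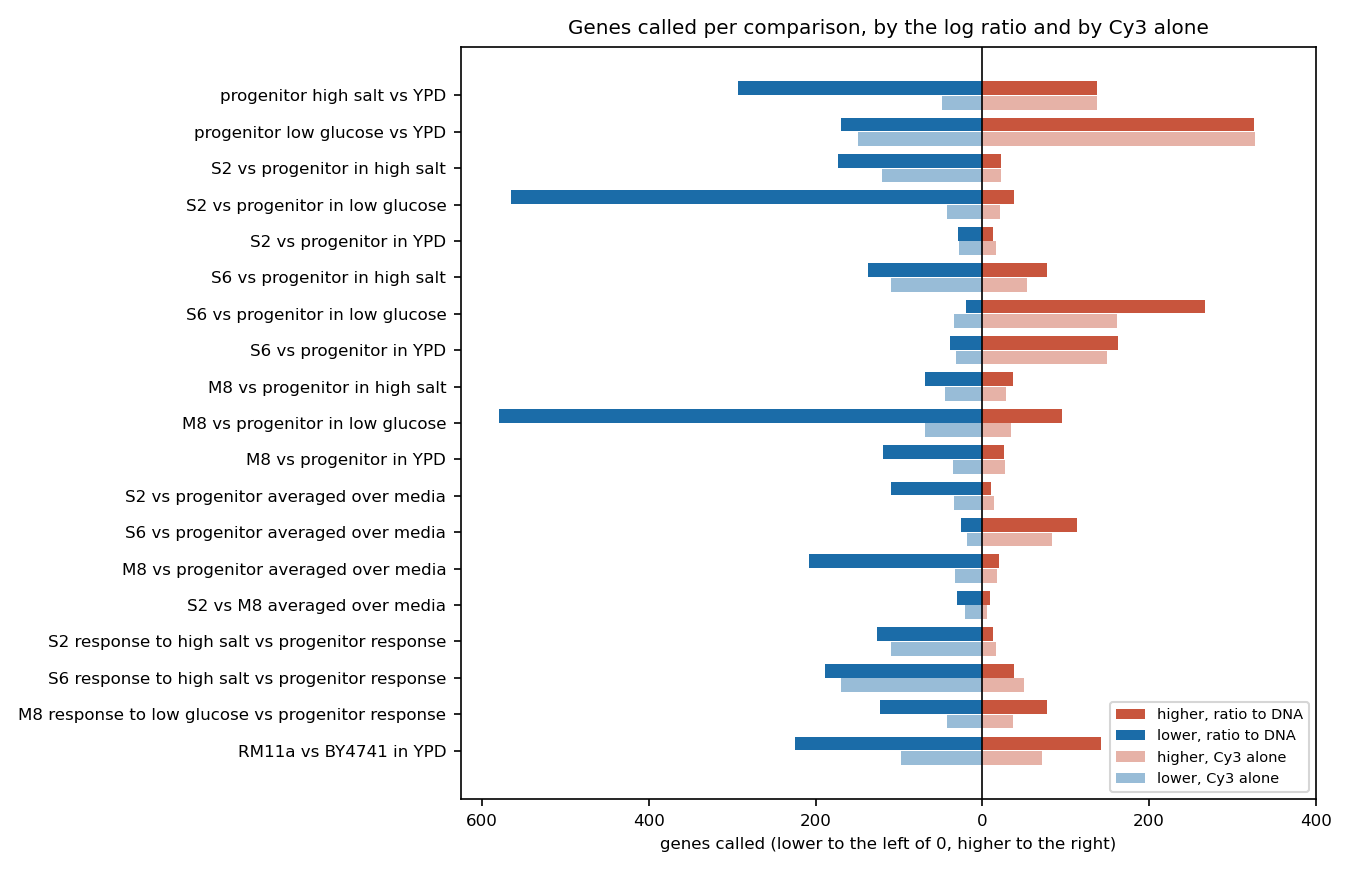
Number of genes called higher and lower (horizontal axis, genes) in each of the 19 comparisons (vertical axis). Low glucose gave the most lower calls for S2 (565) and M8 (580), or 43 and 69 with Cy3 alone (processed, 70 and 127).

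S2 and M8 were then compared with each other, salt line against low-glucose line, on slides they shared (6 arrays against 6). The cell wall mannoprotein genes CWP1 at 1.802 and CWP2 at 1.39 were higher in S2 (SE 0.081 to 0.10, adjusted p 2.9e-08 to 3.5e-08), as was the alcohol dehydrogenase ADH2 at least 2.34-fold higher (SE 0.34, adjusted p 0.011). ADH2 lay at -1.87e-04 after normexp. Lower in S2 than in M8 were COS12 at -1.85, ARO5 at -1.62, the mitochondrially encoded VAR1 at -1.31, CIS1 at -1.23 and FRE4 at -1.21 (SE 0.052 to 0.25, adjusted p 1.9e-10 to 0.0014), and also OYE3 at -1.19, ATR1 at -1.14, RTA1 at -1.14, COX17 at -1.13 and the arginine synthesis gene ARG7 at -1.13 (SE 0.051 to 0.22, adjusted p 6.6e-09 to 0.0017). None of 65 mitochondrial ribosomal protein genes was called (list median -0.48, 64 at an unadjusted limma p below 0.05, adjusted p = 0.049 with an estimated correlation), and 0 members had a positive change. 5 of 65 amino acid biosynthesis genes were lower (list median -0.24 but 0.047 after loess, adjusted p = 0.28 with an estimated correlation). 2 of 8 mitochondrially encoded genes were lower (list median -0.60, adjusted p = 0.43 with an estimated correlation). None of 7 a-cell specific genes was called (list median -0.11 but 2.9e-05 with Cy3 alone, 1 at an unadjusted limma p below 0.05, camera adjusted p = 0.46). None of 4 alpha-cell specific genes was called (list median 0.16, 1 at an unadjusted limma p below 0.05, camera adjusted p = 0.54). Within slides the mitochondrial ribosome medians were -0.37 in high salt, -0.58 in low glucose and -0.49 in YPD, and CWP1 differed by 2.74, 1.24 and 1.43. ARO5 differed by -3.95 in high salt, -0.59 in low glucose and -0.31 in YPD. Limma called 40 of 6224 genes, 9 higher and 31 lower, 28 (8 higher and 20 lower) with slide as a random block, and 0 higher and 4 lower after loess. Within slides the counts were 266 in high salt, 88 in low glucose and 44 in YPD, and the averaged count was 30 without M8 YPD replicate 2 and 62 without M8 YPD replicate 1.

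Genes tied to the adaptation study were listed before the data were examined, namely PMA1, ENA1, ENA2, ENA5, CYC8, TUP1, MKT1, MDS3, GPB1 and GPB2, from what is known of the study. Both sodium-efflux ATPase genes were higher in S2 and S6 in YPD, where ENA1 (YDR040C) differed by 1.76 ± 0.12 in S2 and 2.07 ± 0.12 in S6 and ENA2 (YDR039C) by 2.07 ± 0.12 and 2.35 ± 0.12 (SE, 2 arrays per group, adjusted p 7.0e-09 to 3.9e-07). M8 showed no call there, with -0.079 ± 0.12 for ENA1 and 0.29 ± 0.12 for ENA2. Whether the probes of these neighbouring genes read separate signals was not tested, so their calls need not be independent. On the BY4741 arrays the Cy5 signal of ENA1 lay 2.19 log2 units above the array median, near the 2.24 of ASP3-1 in a repeat. In high salt, where the progenitor itself raised both genes, ENA1 lay at -0.091 in S2 and -0.079 in S6 relative to the progenitor, and ENA2 at 0.26 and -0.011, none of them called. In low glucose ENA1 lay at 0.72 in S2 and 1.18 in S6, and ENA2 at 1.52 and 0.99. Of these, ENA2 in S2 and ENA1 in S6 were called. Averaged over media S2 exceeded M8 by 0.98 ± 0.068 for ENA1 and 0.94 ± 0.068 for ENA2, below the 2-fold minimum (adjusted p 2.3e-07 and 3.5e-07). Within slides the 2 genes differed by -0.13 and -0.16 in high salt, 1.22 and 1.21 in low glucose and 1.84 and 1.79 in YPD. CYC8, a subunit of a general transcriptional corepressor, lay at 0.49 ± 0.091 in S2, 0.48 ± 0.091 in M8 and -0.30 ± 0.10 in S6 over the media, also below 2-fold. The proton pump gene PMA1 lay at -0.10 ± 0.070, -0.28 ± 0.070 and 0.16 ± 0.075 in the same order. For S2 averaged over media, 1 of 10 genes of the adaptation study was higher (list median 0.12, adjusted p = 0.57 with an estimated correlation). For S2 against M8, none of 10 genes of the adaptation study was called (list median 0.18, 7 at an unadjusted limma p below 0.05, adjusted p = 0.25 with an estimated correlation). For S6, 2 of 10 genes of the adaptation study were higher (list median -0.0062 but 1.5e-05 after loess, mean 0.15, camera direction up, camera adjusted p = 0.46). For M8, none of 10 genes of the adaptation study was called (list median -0.13 but 0.14 after loess, 8 at an unadjusted limma p below 0.05, camera adjusted p = 0.997).

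The next question was whether the evolved strains respond differently to their own selective medium than the progenitor does, tested as a difference of responses. For S2 in high salt, the iron uptake genes FIT2 at -5.15 and FIT3 at -4.58 and SNO1 at -4.23 had the lowest relative responses (SE 0.36 to 0.52, adjusted p 3.4e-06 to 5.5e-05). The response was lower for 20 of 25 iron regulon genes (list median -1.65, adjusted p = 0.0022 with an estimated correlation). Higher responses were those of STL1 at 2.71, COS12 at 2.05 and BI4 at 1.82 (SE 0.35 to 0.39, adjusted p 4.9e-04 to 0.0068). BI4 lay at -0.79 without the lower limit on signals. The arginine genes ARG1 at -4.02 and ARG3 at -3.32 responded less (SE 0.15 to 0.28, adjusted p 4.7e-09 to 4.9e-07). The response was lower for 24 of 65 amino acid biosynthesis genes (list median -0.66, adjusted p = 0.047 with an estimated correlation). Both sodium-efflux genes, raised in YPD, responded less, with ENA1 at -1.85 and ENA2 at -1.82 (SE 0.17, adjusted p 6.2e-06 to 7.5e-06). The response was lower for 4 of 6 auxotrophic marker genes (list median -1.46, adjusted p = 0.047 with an estimated correlation). The response was lower for 2 of 23 sodium and cation transport genes (list median 0.038 but -0.021 after quantile scaling, -0.11 after loess and -0.056 with Cy3 alone, mean -0.14, camera direction down, camera adjusted p = 0.46). For S6, whose 1 array in high salt is taken to vary like the other groups, the iron genes ARN2 at -5.77, FIT2 at -5.56 and ARN1 at -4.98 had the lowest responses (SE 0.30 to 0.53, adjusted p 1.4e-07 to 7.4e-06). The response was lower for 23 of 25 iron regulon genes (list median -2.82, adjusted p = 0.0011 with an estimated correlation). Responses of STL1 at 4.36, NFG1 at 2.17 and CWP2 at 1.90 were higher (SE 0.22 to 0.43, adjusted p 1.1e-05 to 6.0e-05). The stress genes HSP12 at -3.98 and DDR2 at -2.69 responded less. The response was lower for 16 of 35 general stress (Msn2/Msn4) targets (list median -0.97, 0 higher and 17 lower adjusted over the list alone, adjusted p = 0.028 with an estimated correlation). ENA2 at -2.36 and ENA1 at -2.15 again responded less. These and the stress list (0.61 in YPD, -0.17 in salt) differed from the progenitor mostly in YPD. The response was higher for 2 of 7 a-cell specific genes (list median 0.87, adjusted p = 0.22 with an estimated correlation), with BAR1 at 1.61 and MFA2 at 1.14 higher (SE 0.28, adjusted p 0.0017 to 0.019). For M8 in low glucose, the phosphate genes PHO84 at 2.996 (a transporter), SPL2 at 2.76 and VTC3 at 2.46 had higher responses than in the progenitor (SE 0.13 to 0.23, adjusted p 1.1e-07 to 7.6e-06). The response was higher for 9 and lower for 1 of 16 phosphate (PHO) regulon genes (list median 1.23, adjusted p = 0.036 with an estimated correlation). Lower responses were those of the hypoxic gene ANB1 at -2.96, AGA2 at -2.88 and the spore wall gene OSW1 at -2.70 (SE 0.26 to 0.57, adjusted p 1.3e-05 to 0.0063). The response was higher for 3 of 36 oxidative phosphorylation genes (list median 0.33, adjusted p = 0.82 with an estimated correlation). The response was higher for 3 and lower for 2 of 24 hexose transport and sensing genes (list median 0.029 but -0.14 after loess, camera adjusted p = 0.71). Limma called 139 genes for S2 (13 higher and 126 lower, or 1 higher and 2 lower after loess), 227 for S6 (38 higher and 189 lower, or 1 and 3 after loess) and 200 for M8 (77 higher and 123 lower, or 102 higher and 106 lower after quantile scaling). The M8 count was 80 (37 higher and 43 lower) with Cy3 alone, 255 after loess, 155 without M8 low glucose replicate 2 and 344 without Progenitor YPD replicate 1.

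RM11a and BY4741 were compared in YPD on a slide of their own (2 arrays each, against BY4741 DNA per the labels). The copper transporter gene CTR3 at 5.02, COS12 at least 16.9-fold higher, HMS1 at least 16.6-fold higher and the polygalacturonase PGU1 at 4.15 were higher in RM11a (SE 0.051 to 0.076, adjusted p 1.8e-06 to 5.3e-06). SDD1 at 3.74, NFG1 at 3.71 and the dipeptide transporter PTR2 at 3.65 followed (SE 0.050 to 0.060, adjusted p 2.3e-06 to 3.5e-06). With Cy3 alone, compressed by normexp on RM11a replicate 1, COS12, HMS1, PGU1 and SDD1 lay at 1.40, 1.51, 1.60 and 1.47. RSC30 at 4.59, IMD1 at 3.87 and MST27 at 3.66 were called higher by the ratio (SE 0.062 to 0.32, adjusted p 2.3e-06 to 4.3e-04), but with Cy3 alone they lay at 1.08, 0.028 and -0.55. Their Cy5 signal differed by -3.09, -3.79 and -4.21 between RM11a and BY4741 arrays. Lower in RM11a were the phosphate transporter PHO89 at -5.66, the acid phosphatase PHO12 at -4.57, the hexose transporter HXT8 at least 18.8-fold lower, QDR2 at -5.34 and SRD1 at least 34.8-fold lower (SE 0.052 to 0.22, adjusted p 1.6e-06 to 1.0e-04), and also the daughter-cell genes DSE1 at -4.99 and DSE2 at -4.13, with NDJ1 at least 14.9-fold lower, PRM9 at least 11.6-fold lower and mitochondrially encoded ATP8 at least 15.7-fold lower (SE 0.049 to 0.26, adjusted p 1.6e-06 to 2.0e-04). With Cy3 alone PHO89, QDR2, SRD1, NDJ1, HXT8 and PRM9 lay at -3.13, -2.67, -2.74, -2.04, -1.73 and -1.17. ATP8 lay at -0.74 with Cy3 alone and at 1.46 in Cy5. 12 of 16 phosphate (PHO) regulon genes were lower (list median -1.36 but 0.079 after loess, adjusted p = 0.62 with an estimated correlation), with PHO5 at -3.26 and SPL2 at -3.08 (SE 0.066 to 0.090, adjusted p 8.1e-06 to 1.8e-05). 6 of 7 mitochondrially encoded genes were lower (list median -2.77 but -0.65 with Cy3 alone, adjusted p = 0.62 with an estimated correlation). 7 of 36 oxidative phosphorylation genes were higher (list median 0.53 but -0.094 after loess, adjusted p = 0.62 with an estimated correlation), with CYC1 at 2.26 and CYT1 at 1.86 (SE 0.052 to 0.053, adjusted p 1.1e-05 to 1.6e-05). 2 of 28 glucose-repressed carbon metabolism genes were higher and 3 were lower (list median -0.19 but 0.012 with Cy3 alone, camera adjusted p = 0.25). 7 of 46 cell wall mannoprotein and hypoxic genes were higher and 5 were lower (list median -0.17 but 0.037 after loess and 0.12 with Cy3 alone, camera adjusted p = 0.83), with CWP1 at 2.87 highest (SE 0.044, adjusted p 3.0e-06). Of the adaptation-study genes, GPB2 at -1.02 was lower (SE 0.045, adjusted p 6.3e-05). Limma called 367 of 5754 genes, 142 higher and 225 lower. The split was 196 and 88 after loess, 71 and 98 with Cy3 alone and 122 and 166 with processed Cy3. Of the 367 calls, 50 had a Cy5 reference difference of at least 2-fold between the strains' arrays and 118 moved at least 2-fold the same way in Cy3 alone.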

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

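Of the tests in this part, those of slides and of mixed cells for the mating genes, of weak Cy5 signal in low glucose and of RM11a DNA in the reference were chosen only after the result was seen. The response to the selective medium differed between an evolved strain and the progenitor, by limma's test of the difference itself, for 139 genes in S2 under high salt (3 after loess). It differed for 227 genes in S6 under high salt, where S6 had 1 array (4 after loess). In M8 under low glucose it differed for 200 genes, for 80 with Cy3 alone, 86 with only the arrays compared, 4 with normexp, 155 without M8 low glucose replicate 2 and 344 without Progenitor YPD replicate 1.

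The 1st pattern is the mating genes, of which alpha-cell genes were higher and a-cell genes lower in S2 and M8 than in the progenitor in all 3 media (3 of 4 alpha-cell genes called for M8 in high salt), although strain and slide coincide in these comparisons. A general difference between slides is argued against by the median absolute Cy3 change of the 11 a-cell and alpha-cell genes, 4.75, which lay at percentile 100 of 10000 random lists of genes of like level, the highest of which reached 0.256. In S2 and M8 the 7 a-cell genes kept a median 9.77% of progenitor Cy3 (quartiles 2.71 and 11.1). MFA2 fell by -6.48, so only a lower share of a cells stays open. As a hypothesis, S2 and M8 may be cells of the opposite mating type to the progenitor and S6, which no label states and which was not tested apart from these genes. Cy5 of the brightest of them moved with Cy3 (MF(ALPHA)1 2.20, MFA1 -1.11, MFA2 -1.12), so Cy3 read in Cy5 stays open.

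The 2nd pattern is the lower calls in low glucose, 565 in S2 and 580 in M8 (400 shared). Cy3 alone gave 43 and 69 and processed Cy3 70 and 127. Averaged over media, lower calls lay at median Cy3 level percentiles of 8.85 and 7.39. The 565 and 580 genes lay at 8.02 and 9.23, with median ratio changes of -1.41 and -1.42. Weak Cy5 signal on the slide of S2 and M8 is argued against as the whole cause. These genes' Cy5 was higher by a mean of 0.351 over both strains (upper quartiles 0.54 and 0.56). For higher calls weak Cy5 stays open (medians -0.77 in Cy5 and 0.44 in Cy3 in S2, -0.46 and 0.77 in M8). Depending on scaling, Cy3 of lower calls changed by -1.09 (median-centred, S2), -0.16 and -0.21 (Cy3 alone) or -0.31 and -0.41 (processed Cy3). DNA carried into the progenitor's RNA would tie Cy3 to Cy5 more closely on progenitor than on S2 arrays, but the difference in mean r was -0.0318. Raised dim signals on 1 progenitor array alone are argued against by 584 lower calls in S2 without Progenitor low glucose replicate 2 and 399 without replicate 1. The slide against the strains also stays open, since they cannot be told apart here. The 10th percentile of centred Cy3 lay at -2.39 and -2.52 on both progenitor arrays and -1.94 and -2.02 on those of S6, on the same slide. On those of S2 and M8 it lay at -3.20 to -3.53.

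The 3rd pattern is the reference channel of the arrays labelled RM11a, which no comparison used by itself and which the labels give as BY4741 DNA. On RM11a arrays Cy5 was brighter by at least 6.936 log2 units for HIS3 and 7.267 for MET17, bounds set by the lowest signals of the 2 BY4741 arrays, where both were below background, and 86 probes were at least 4-fold dimmer and 5 brighter. For most of the 86 dimmer probes Cy3 read in the Cy5 channel is argued against, since 18.6% lay above the median Cy3 level. For all other probes it stays open. Signal for both genes (at least 6.94) is what RM11a DNA in place of BY4741 DNA would give, because BY4741 is known to lack them. RM11a DNA may therefore have been the reference, while DNA of another strain with both genes was not tested.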

How the results depend on the processing

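The alternatives tested only after the data were seen were normexp with an offset of 50, processed signals without their lower limit, 50 added to them, Cy3 processed signals alone, the looser Cy5 filter and the averages without low glucose. The brightest-probe alternative was not run, since each gene has 1 probe. For the counts below, the cause of a move was not tested unless given. None of the 19 counts of calls moved by over 1.5 times with trend and robust variance, without the lower limit or with the looser Cy5 filter, nor any of the 18 with the deposited value table. With the replicate number as a block none of the 19 moved either (for example 434 in progenitor salt), and the numbers do not pair the arrays, since 19 of 55 correlations of replicate differences were over 0.1 (median 0.0010, -0.58 to 0.67).

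Loess gave 1 in progenitor salt, 6 in progenitor low glucose, 69 in S2 high salt, 75 in S2 YPD, 3 in S6 high salt, 8 in S6 low glucose, 0 in S6 YPD, 46 in M8 high salt, 80 in M8 YPD, 2 in S6 averaged, 91 in M8 averaged, 4 in S2 against M8, 3 in S2 response and 4 in S6 response. Quantile scaling gave 292 in S2 low glucose, 417 in M8 low glucose, 90 in M8 YPD, 38 in S2 averaged and 66 in M8 averaged. Cy3 alone gave 185 in progenitor salt, 64 in S2 low glucose, 103 in M8 low glucose, 62 in M8 YPD, 48 in S2 averaged, 50 in M8 averaged, 26 in S2 against M8, 80 in M8 response and 169 in RM11a. Cy3 processed signals alone gave 107 in S2 low glucose, 227 in M8 low glucose, 63 in S2 averaged, 78 in M8 averaged and 133 in M8 response. No background subtraction gave 213 in progenitor salt, 372 in S2 low glucose, 67 in M8 high salt, 344 in M8 low glucose, 55 in M8 YPD, 35 in S2 averaged, 83 in S6 averaged, 43 in M8 averaged, 23 in S2 against M8 and 129 in M8 response. Adding 50 gave 255 in progenitor salt, 68 in M8 high salt, 433 in M8 low glucose, 55 in M8 YPD, 41 in S2 averaged, 91 in S6 averaged, 54 in M8 averaged and 23 in S2 against M8. Normexp gave 50 in progenitor salt, 204 in progenitor low glucose, 56 in S2 high salt, 221 in S2 low glucose, 19 in S2 YPD, 31 in S6 high salt, 32 in S6 low glucose, 55 in S6 YPD, 19 in M8 high salt, 141 in M8 low glucose, 24 in M8 YPD, 40 in S2 averaged, 47 in S6 averaged, 68 in M8 averaged, 13 in S2 response, 23 in S6 response, 4 in M8 response and 0 in RM11a. With normexp limma called 0 genes in RM11a, where 229 had an unadjusted p below 0.05. The strict filter, which tests fewer genes, gave 261 in progenitor salt, 282 in S2 low glucose, 182 in S6 low glucose, 374 in M8 low glucose, 76 in M8 YPD, 54 in S2 averaged and 84 in M8 averaged. No filter gave 571 in RM11a. Fitting only the arrays compared gave 190 in progenitor salt, 15 in S2 YPD, 191 in S6 low glucose, 17 in M8 YPD, 126 in S6 response and 86 in M8 response. Slide as a random block gave 67 in S2 averaged. Leaving out low glucose gave 77 in S2 averaged, 98 in M8 averaged and 74 in S2 against M8. No fold minimum, which can only add calls, gave 1965 in progenitor salt, 2743 in progenitor low glucose, 1214 in S2 high salt, 3114 in S2 low glucose, 136 in S2 YPD, 619 in S6 high salt, 1465 in S6 low glucose, 1184 in S6 YPD, 1215 in M8 high salt, 3220 in M8 low glucose, 1304 in M8 YPD, 2654 in S2 averaged, 1515 in S6 averaged, 3434 in M8 averaged, 1966 in S2 against M8, 309 in S2 response, 574 in S6 response, 1156 in M8 response and 3629 in RM11a. Loess called 0 genes for S6 in YPD, where 619 had an unadjusted limma p below 0.05. Of 532 tests of gene lists camera called 266, 240 after quantile scaling and 251 with Cy3 alone, but 42 with an estimated correlation, and fry called 252. With 1 array left out, which leaves a lone array assumed to vary like the other groups, counts ran from 225 to 753 in progenitor salt, 28 to 246 in S2 YPD, 70 to 445 in M8 YPD, 83 to 235 in S2 averaged, 123 to 371 in M8 averaged, 30 to 62 in S2 against M8 and 155 to 344 in M8 response. The arrays behind these ends are named in the comparisons (for progenitor salt as in S2 averaged), and the other 12 counts stayed within 1.5 times.

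Of the 342 changes of named genes, loess turned the sign of 80, with these log2 changes. In progenitor salt ASG7 lay at 0.16, BRP1 at 0.035, FIT2 at -0.31, GPD1 at -0.0041, PRM1 at 0.048 and VAR1 at 0.16. In progenitor low glucose ENO2 lay at 0.19, GAP1 at -1.40, HSP12 at -0.0050, HXT1 at 0.087 and PHO84 at 0.45. In S2 high salt FIT2 lay at 0.052, FIT3 at 0.13, HXT5 at 0.27, MF(ALPHA)1 at -0.27 and STL1 at -0.42. In S2 low glucose MF(ALPHA)1 lay at -0.39, MFA1 at 1.04 and MFA2 at 0.95. In S2 YPD ENA1 lay at -0.076. In S6 high salt GAL4 lay at -0.074, IMA1 at -0.57 and STL1 at -0.14. In S6 low glucose ENA1 lay at -0.0077 and HXT4 at -0.32. In S6 YPD ENA1 lay at -0.075, ENA2 at -0.013, FIT2 at -0.32, FIT3 at -0.071, GLC3 at -0.19 and GSY1 at -0.10. In M8 high salt CWP2 lay at 0.36, HMRA1 at 2.19 and MF(ALPHA)1 at -0.23. In M8 low glucose HSP12 lay at 0.051, HXT4 at -0.44, MF(ALPHA)1 at -0.41, MFA1 at 1.13, MFA2 at 0.81 and SPL2 at -0.24. In M8 YPD MF(ALPHA)1 lay at -0.062 and MFA1 at 0.11. In S2 averaged BAR1 lay at 0.23, MF(ALPHA)1 at -0.19 and MFA1 at 0.26. In S6 averaged AGA1 lay at 0.067, ALD4 at -0.084, COS1 at 0.19, ENA1 at -0.021, ENA2 at -0.025, GAL4 at -0.077, IMD2 at 0.0042, REG2 at -0.11 and TMA10 at -0.095. In M8 averaged ASG7 lay at 0.31, BAR1 at 0.31, CCW22 at 0.080, HMLALPHA1 at -0.011, HMRA1 at 0.95, HSP12 at 0.077, MF(ALPHA)1 at -0.23 and MFA1 at 0.41. In S2 against M8 ARG7 lay at 0.10, CWP2 at -0.16 and OYE3 at 0.037. In S2 response FIT3 lay at 0.30 and STL1 at -0.11. In S6 response CWP2 lay at -0.24, ENA1 at 0.10, FIT2 at 0.61, MFA2 at -0.058 and STL1 at -0.55. In M8 response OSW1 lay at 0.016, PHO84 at -0.58 and SPL2 at -0.57. In RM11a CYC1 lay at -0.064, DSE2 at 0.15, PHO5 at 2.02, SDD1 at -0.21 and SPL2 at 0.37. Other settings turned MST27 in RM11a (-0.55 with Cy3 alone), TKL2 in M8 averaged (0.025 with normexp), ADH2 in S2 against M8 (-1.9e-04 with normexp), BI4 in S2 response (-0.79 without the lower limit), IMD1 in RM11a (-0.22 with Cy3 processed signals alone) and MST27 in RM11a (-0.94 with Cy3 processed signals alone). Without a change of sign, 215 of these changes lost their call with loess, 133 with normexp, 34 with Cy3 alone, 24 with only the arrays compared, 23 with no background subtraction, 16 with 50 added, 14 with Cy3 processed signals alone, 11 with slide as a random block, 11 without low glucose, 10 with quantile scaling, 2 without the lower limit, 1 with the deposited value table and at most 8 with 1 array left out. As for signal over background, 87.7 to 99.9% of probes per array lay well above background in Cy3.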

Other observations

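In this part the test of ASP3 was chosen only after the result was seen. In S6 in low glucose (2 arrays against 2), the high-affinity hexose transporter gene HXT4 at 2.58 and the repressor gene MIG2 at 1.84 were higher (SE 0.11 to 0.16, adjusted p 4.0e-08 to 8.9e-08). 9 of 24 hexose transport and sensing genes were higher (list median 0.68, adjusted p = 0.066 with an estimated correlation). The median was 0.24 with Cy3 alone and 0.056 after loess, and raised dim signals stay open. In YPD the glycogen genes GLC3 at 1.96 (branching enzyme), GPH1 at 1.503 and GSY1 at 1.35 (glycogen synthase) were higher in S6 (SE 0.12 to 0.14, adjusted p 6.5e-08 to 7.8e-06). 5 of 18 trehalose and glycogen genes were higher (list median 0.59, adjusted p = 0.064 with an estimated correlation). In high salt, where S6 had 1 array, the arginine synthesis gene ARG1 at -4.76 and the serine synthesis gene SER3 at -2.39 were lower (SE 0.12 to 0.24, adjusted p 1.0e-08 to 1.1e-08). 19 of 65 amino acid biosynthesis genes were lower (list median -0.61, adjusted p = 0.15 with an estimated correlation). The succinate dehydrogenase subunit genes SDH1 at 1.08, SDH2 at 1.13, SDH3 at 1.14 and SDH4 at 1.11 responded more to salt in S6 than in the progenitor, by limma with that 1 array taken to vary like the other groups (SE 0.19 to 0.25, adjusted p 0.0016 to 0.0094). The response was higher for 4 of 19 tricarboxylic acid cycle genes (list median -0.070, mean 0.22, camera direction up, camera adjusted p = 0.26).

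A set of 100 splits of the arrays within each medium, out of 108 possible, was counted for each averaged comparison. The real split, 1 of 100, alone called as many genes in each. The lead was clear only for S6, so chance is not excluded for the others. Replicates that may be technical leave differences between cultures of 1 strain untested. The real count was 120 against a highest other of 119 for S2, 139 against 94 for S6, 228 against 211 for M8 and 40 against 38 for S2 against M8. For S2 and M8 that highest other split parted the strains as in the real one in high salt and low glucose and mixed them in YPD, and for S2 against M8 it exchanged the strains in low glucose and YPD. The real split of S2 or M8 from the progenitor is also the split of their slides, and with slide as a random block the counts were 67 and 168.

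The 7 genes of the ASP3 repeat had median changes in S6 of -2.55 in high salt, -2.60 in low glucose and -2.59 in YPD, a range of 0.0454, while 10 flanking genes lay at 0.10, 0.045 and -0.12, as fewer copies of the repeat might give. Of the 7 probes 4 are those of the near-identical ASP3 copies, and the other 3 genes had medians of -2.74, -2.22 and -2.47. With Cy3 alone the medians of the 7 were -2.38, -2.79 and -2.55. In M8 the 7 genes lay lower as well, at -0.73, -1.26 and -0.68, and lower expression of the repeat without a loss of copies was not tested. The DNA of S6 was not measured on these arrays. No chromosome as a whole moved by what a gain or loss would give, since the chromosome median of log2 Cy3 furthest from 0 was 0.0456 in S2 (chromosome 1), -0.0580 in S6 (chromosome 1) and -0.0359 in M8 (chromosome 6).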
